A study of Physcomitrium patens with 8 samples.

How the data were processed

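The measurements come from 8 two-colour oligonucleotide arrays of the moss Physcomitrium (Physcomitrella) patens. On each array, RNA of gametophyte protonema, the haploid filamentous tissue, was hybridised together with RNA of sporophytes, the diploid spore-bearing generation, at an early or a mid stage. Per the labels' protocols, RNA of each tissue was labelled directly as total RNA with ULS dyes, which attach chemically to nucleic acid without copying it. Each stage had 3 sporophyte samples, each paired with its own gametophyte sample, so there were 6 gametophyte samples in all. The series design describes these as separate biological replicates. The third sample pair of each stage was hybridised a second time with the dyes exchanged.

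Per the file headers, the deposited spot intensity values were extracted with Agilent Feature Extraction 9.5.3.1, which gives the mean brightness of a spot and the median of its local background in each channel without subtraction. Per the file headers, the deposited processed intensity had its spatially detrended background subtracted and its dyes balanced by a linear and LOWESS step with a smoothing factor of 0.25, with substitute values for spots near background. The deposited log10 ratio of Cy5 over Cy3 was made from those processed signals, per the file headers. The deposited table of values for the whole series was the same log10 ratio to its rounding in 100% of moss spots on each array, with the dye-swap arrays not turned. The median of each of its columns was 0, and 21.8% to 29.3% of spots per array were listed at exactly 0. Its scale and direction were therefore settled, and no centring was found beyond that of the scanner software.

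Each array held 42801 spots, of which 41384 were moss probes and 1417 were controls, 153 of them negative controls. The moss spots carried 28178 probe identifiers, each a 60-nt oligonucleotide; 13206 identifiers had 2 spots of identical sequence and 14972 had 1. The files did not pair probes with gene names, descriptions or positions, and 0 identifiers matched the reference table of RefSeq genes used here. Probes are therefore reported by identifier and sequence. The lists of gene groups fixed before the data were examined, such as light harvesting, cell wall or stomata genes, need gene descriptions, so no list was tested. The meaning of a plus sign at the end of 102 spot names is not stated.

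Mean signals were corrected with the median local background by normexp with an offset of 50 and normalised within each array by loess with a span of 0.3, using limma 3.58.1 in R 4.3.3. Control spots had weight 0, and 9 outlier spots were left out. Each log2 ratio was turned to sporophyte over gametophyte by the dyes in the labels. Spots of one identifier were averaged, and the dye-swap pair was averaged to 1 replicate. A probe was tested if it was well above background, in the channel of that tissue, on every array of at least 1 of the 4 sets of channels (early sporophyte, mid sporophyte and the gametophyte of either set of arrays). This kept 14920 probes. A linear model with a mean per stage was fitted to the 6 log2 ratios with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The stages were compared on split channels after Aquantile normalisation between arrays, and the gametophyte channels of the 2 sets of arrays were compared in the same way. A dye effect was estimated from all 8 arrays with the replicate as a random block.

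Named probes were chosen by a rule fixed before the data were examined. With no gene descriptions, it takes at most 2 probes that rose and 2 that fell per comparison, the largest changes among those past the threshold, at least 2-fold and alike in all replicates (for the stages, without overlap of the 3 and 3 values). Where a probe was not well above background on any array of the dimmer group, its fold is a lower bound. The bound sets the mean of the brighter group against, per array, the higher of the probe's own signal and the lowest signal among probes well above background, on channels after loess and Aquantile. Such bounds depend on the background correction and are open to dye bias, since 2 of 3 replicates per stage had 1 dye orientation.

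The number of arrays limits the precision. The raw signal of the median moss probe was 1.19 to 1.32 times that of the median negative control, and the local background of 41 to 65 intensity units lay far below the negative controls at 1045 to 1592. After normexp the negative controls still held 362 to 586 units, so the log2 ratios of dim probes are compressed. Processed signals, from which a higher background had been taken, gave log2 ratios 1.58 times as large over all tested probes for the mean of both stages (r across probes 0.953). The SD of duplicate spots, over all identifiers with 2 spots, was 0.15 to 0.19 on the log2 scale. The median SD between replicates of tested probes was 0.12 at the early and 0.14 at the mid stage. Dye bias adds to this. Between the 2 dye orientations of early sample 3, log2 ratios correlated across tested probes at r = 0.755, with an SD of 0.30 over the probes. For mid sample 3 the values were r = 0.709 and 0.32.

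The fits were tested on simulated data with the number of probes and the spread of the real ones, in which 200 probes were changed by 0.5 or 1 on the log2 scale. Of 100 probes changed by 0.5, the early fit recovered 53, the mid fit 50, the mean of both stages 74, the difference of ratios 19 and the split sporophyte channels 1. Of 100 changed by 1, they recovered 82, 77, 89, 62 and 43. Changes of 0.5 between stages would therefore mostly be missed. Recovery against gametophyte may differ in the real data, where far more than 200 probes were called, since the adjustment depends on the share of changed probes. In the simulated dye effect, 99 of 100 were recovered but 22.4% of calls were false, and the correlation within a replicate was estimated at 0.84 where 0.7 had been simulated. The count of dye effects is therefore open to overstatement.

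Early arrays all lay on 1 slide and mid arrays on another, so slide and stage differ only through the gametophyte channel on each. Alternatives covered the background correction, the normalisation, the filter, single spots, a 2-fold threshold, the deposited ratios, dye terms, pairing and leaving out each replicate. The dye effect from the dye-swap pairs alone, the removal of a trend on GC content by loess with a span of 0.5, the similarity of probes to each other and the fits without probes of repeated sequence were added after seeing the data. A first analysis asked whether pairs of similar probes change alike or seldom change 2-fold. It was dropped for the comparison of repeated sequences once their shared pattern over the replicates was seen, and the minimum of 3 similar probes was set then. Probes were aligned to each other with blastn 2.17.0, and 2 probes counted as similar with at least 80% identity over at least 40 nt on either strand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.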

Results

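The arrays compared the 2 generations of the moss life cycle, in which a haploid gametophyte bears a diploid sporophyte. Protonema aged 7 days was the only gametophyte tissue. Tissue type and culture therefore differed along with the generation and cannot be told apart from it. Sporophytes were raised after 3 weeks at 15 degrees C and 2 hours of flooding for fertilisation, and foot and calyptra remnants were removed from the early columnar capsules and from the ovoid to near-spherical green mid capsules. At least 400 sporophytes went into each extraction and up to 1600 into each array replicate. There were 3 early and 3 mid sporophyte samples, each on an array with its own gametophyte sample. Of 28178 probes, 13145 to 16147 were well above background in a channel, and 10581 were so in both channels of all 8 arrays. The sporophyte channel had on average 622 more such probes than the gametophyte channel of the same pair (SD 694, n = 6 pairs), with 5 of 6 pairs higher. The pairs ranged from -165 to 1882, and early sample 3, at 1882, lay far above the next highest pair at 781. The 2 highest pairs, early sample 3 and mid sample 3, average both dye orientations. In early sample 3, sporophyte and gametophyte had 14769 and 13629 such probes with the sporophyte in Cy5, and 15911 and 13287 in Cy3. In mid sample 3 they had 16147 and 15913 with it in Cy5, and 14473 and 13145 in Cy3. The other pairs had the sporophyte in Cy5 only, so dye bias may lower their differences. The mean difference did not pass an exact two-sided sign permutation test (p = 0.0625, Benjamini-Hochberg adjusted p = 0.0625 over 2 measures). The smallest possible p is 0.0312.

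Sporophyte and gametophyte differed widely. Probe Pp_162511 (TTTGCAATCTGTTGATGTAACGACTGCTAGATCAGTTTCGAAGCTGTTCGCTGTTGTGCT) was 23.7-fold higher in sporophyte over both stages, with a log2 ratio of 4.57 ± 0.43 (SD, n = 6) and an adjusted p of 1.83e-05. Pp_72790 (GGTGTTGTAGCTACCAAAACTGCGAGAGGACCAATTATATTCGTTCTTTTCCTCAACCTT) was at least 10.1-fold higher, since it was not well above background in gametophyte on any of 8 arrays; its fitted log2 ratio was 4.32 ± 0.48 (SD, n = 6) and its adjusted p 1.96e-05. Pp_100530 (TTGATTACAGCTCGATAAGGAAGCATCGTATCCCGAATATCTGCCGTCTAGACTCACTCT) was 16.6-fold lower in sporophyte, where 7 of 8 arrays measured it well above background, with a log2 ratio of -4.05 ± 0.38 (SD, n = 6) and an adjusted p of 5.62e-06. Pp_184189 (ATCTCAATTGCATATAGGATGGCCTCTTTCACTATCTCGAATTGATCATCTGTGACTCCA) was 14.5-fold lower, with a log2 ratio of -3.86 ± 0.31 (SD, n = 6) and an adjusted p of 1.74e-05. In the mean of both stages, 10367 of 14920 tested probes passed the threshold in limma, 5544 higher and 4823 lower in sporophyte. The balance of directions depended on the scaling, with 4627 higher and 4768 lower with processed signals, 8554 and 8784 with no filter on dim probes, and 6169 and 4332 with median centring in place of loess. Most of these differences were small: the median absolute log2 ratio of called probes was 0.39, and 1085 probes were at least 2-fold apart, 612 higher and 473 lower. With normexp, the balance beyond 4-fold tilted to the sporophyte, with 130 probes higher and 40 lower. Beyond 8-fold 17 were higher and 7 lower. With processed signals 1481 probes were at least 2-fold higher and 1372 lower, and 811 were at least 4-fold apart, their directions not counted. The size of the ratios depended on the background correction. With processed signals Pp_72790 had a log2 ratio of 5.26, Pp_100530 of -5.88 and Pp_184189 of -4.64, and 2853 probes were at least 2-fold apart. With no background correction the same probes had log2 ratios of 2.06, -2.96 and -3.21, which for Pp_72790 lies below the bound given above.

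Some probes were seen in 1 generation alone. On all 8 arrays, 179 probes were well above background in sporophyte and not in gametophyte on any, and 93 were so in gametophyte and not in sporophyte. Their median fitted log2 ratios in the mean of both stages were 1.01 and -1.17, which are not bounds. The smallest were 0.28 and -0.42, so the flags do not show absence from the other tissue. A set of 10581 probes was well above background in both tissues on every array, and 8710 in neither on any.

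The first stage compared was the early sporophyte. Pp_162511 was 23.9-fold higher in early sporophyte than in gametophyte, with a log2 ratio of 4.58 ± 0.43 (SD, n = 3) and an adjusted p of 0.000136. Pp_71898 (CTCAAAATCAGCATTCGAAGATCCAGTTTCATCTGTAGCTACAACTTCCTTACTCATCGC) was at least 16.9-fold higher, as it was not well above background in gametophyte on any of the 4 early arrays; its fitted log2 ratio was 4.38 ± 0.30 (SD, n = 3), with an adjusted p of 0.000182. Pp_100530 was 20.7-fold lower, with a log2 ratio of -4.37 ± 0.09 (SD, n = 3) and an adjusted p of 2.96e-05, and 3 of 4 early arrays measured it well above background in sporophyte. Pp_184189 was 15.9-fold lower, with a log2 ratio of -3.99 ± 0.41 (SD, n = 3) and an adjusted p of 0.000123. In all, 7812 probes passed the threshold, 3923 higher and 3889 lower, and 1053 of them were at least 2-fold apart, 576 higher and 477 lower. That balance was 3054 higher and 3561 lower with processed signals, and 4342 and 3484 with median centring. At least 2-fold apart with processed signals were 2652 probes, 1326 higher and 1326 lower. With processed signals, Pp_71898 had a log2 ratio of 6.23 and Pp_100530 of -6.21. With no background correction these probes had log2 ratios of 2.55 and -3.09, which for Pp_71898 lies below the bound given above. Without early sample 1 the count of called probes fell to 4567.

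The mid sporophyte gave a like picture. Pp_162511 was 23.6-fold higher than in gametophyte, with a log2 ratio of 4.56 ± 0.52 (SD, n = 3) and an adjusted p of 0.000152. Pp_72790 was at least 12-fold higher, with no mid array measuring it well above background in gametophyte, a fitted log2 ratio of 4.48 ± 0.50 (SD, n = 3) and an adjusted p of 0.000165. Pp_184189 was 13.3-fold lower, with a log2 ratio of -3.74 ± 0.18 (SD, n = 3) and an adjusted p of 0.000152, and Pp_100530 was 13.3-fold lower, with a log2 ratio of -3.73 ± 0.19 (SD, n = 3) and an adjusted p of 7.85e-05. In all, 8197 probes passed the threshold, 4207 higher and 3990 lower, and 1088 were at least 2-fold apart, 597 higher and 491 lower. The balance turned here too, to 3281 higher and 3804 lower with processed signals and to 3996 and 4114 with no background correction, against 4678 and 3503 with median centring. At least 2-fold apart with processed signals were 2842 probes, 1408 higher and 1434 lower. With processed signals, Pp_72790 had a log2 ratio of 5.37 and Pp_100530 of -5.55. With no background correction these probes had log2 ratios of 2.18 and -2.83, the former below its bound. Without mid sample 1 the count of called probes fell to 5457, and without mid sample 2 to 4502.

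**Figure D1:**
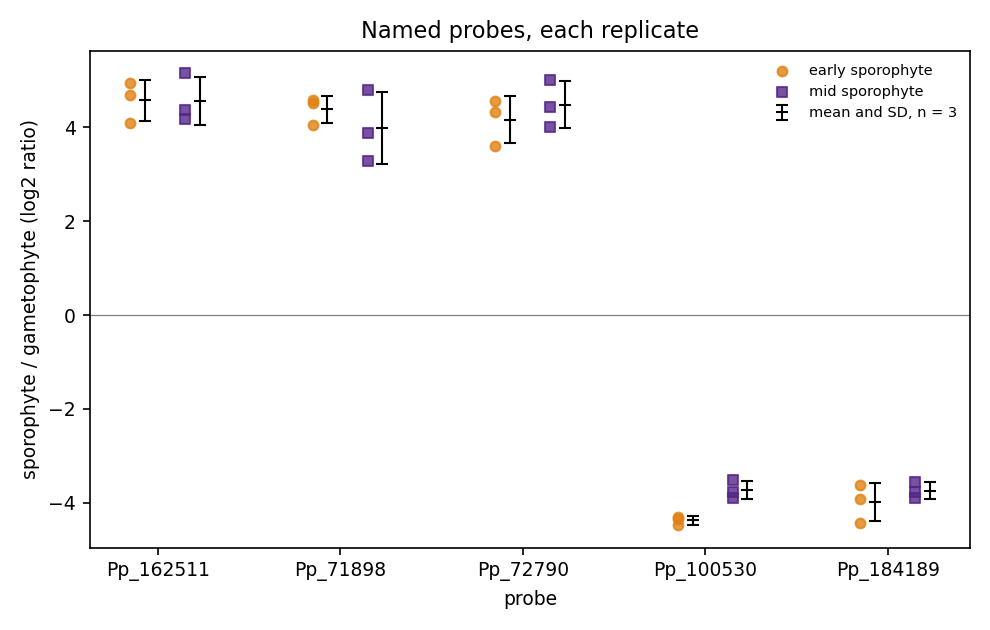
Log2 ratio of sporophyte over gametophyte (vertical axis) for the 5 probes named against gametophyte, at most 2 in each direction per comparison (horizontal axis), with each early (circle) and mid (square) replicate and the mean and SD of 3. Pp_162511, Pp_71898 and Pp_72790 lie above 0 and Pp_100530 and Pp_184189 below 0 in all 6 pairs.

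The early and mid ratios were then set against each other. They rest on different gametophyte samples, so they share no control samples, though both are open to the same dye bias. The tests of both stages also share 1 estimate of the spread of each probe, which favours probes of low spread in both lists. The counts for independent lists given below leave this out. Across the 14920 probes, which are not independent replicates, the early and mid log2 ratios correlated at r = 0.940 with a covariance of 0.317, and at r = 0.929 with a dye term in the fit. Of the probes higher in early sporophyte, 3346 were also called higher in mid sporophyte, against 1106 for independent lists. Of those lower, 3449 were called lower at both stages, against 1040. Only 2 probes were called in opposite directions. The 6795 probes called in the same direction at both stages fell to 4327 without early sample 1 and to 4235 without mid sample 2. At the 2-fold level, 429 probes were higher at both stages, against 23 for independent lists, and 379 were lower at both, against 15.7.

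**Figure D2:**
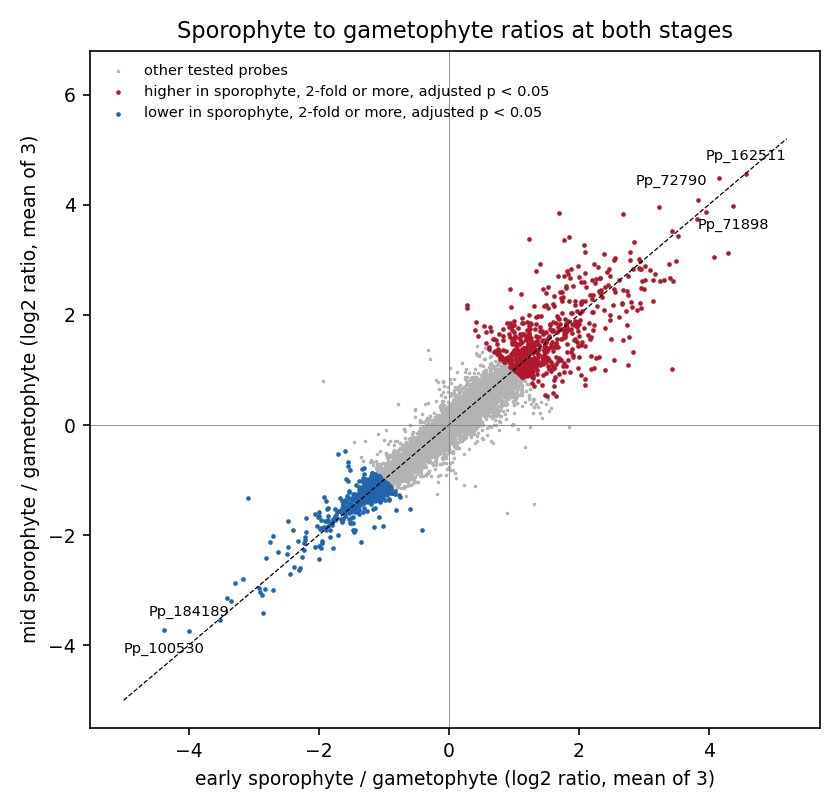
Log2 ratio of early sporophyte over gametophyte (horizontal axis) against that of mid sporophyte over gametophyte (vertical axis), each the mean of 3 replicates, for 14920 tested probes. Probes at least 2-fold higher (red, 612) or lower (blue, 473) in the mean of both stages lie along the dashed line of equality, with r = 0.940 over all probes.

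The series design compares mid with early sporophyte on split channels. Pp_222159 (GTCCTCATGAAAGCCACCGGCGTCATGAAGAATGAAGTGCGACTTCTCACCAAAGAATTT) was at least 2.62-fold higher in mid sporophyte, since no early array measured it well above background in sporophyte, and Pp_94177 (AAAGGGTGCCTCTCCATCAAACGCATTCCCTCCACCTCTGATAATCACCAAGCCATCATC) was 3.1-fold higher. Their adjusted p-values were 0.0323 and 0.0248. Pp_166762 (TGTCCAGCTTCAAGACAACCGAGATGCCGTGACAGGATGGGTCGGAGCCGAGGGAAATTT) was at least 7.75-fold lower and Pp_72617 (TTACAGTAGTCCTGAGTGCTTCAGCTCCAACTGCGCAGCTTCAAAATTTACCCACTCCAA) at least 3.70-fold lower, with adjusted p-values of 0.0402 and 0.0248, and neither was well above background in sporophyte on any mid array. The bounds of Pp_166762 and Pp_72617 equal their fitted folds, since their own signals set the bound. Pp_94177 measured 13.67 ± 0.16 (SD, n = 3) in early and 15.30 ± 0.07 (SD, n = 3) in mid sporophyte on the log2 scale, while Pp_166762 measured 12.27 ± 1.03 and 9.32 ± 0.06. With processed signals the log2 changes of Pp_222159, Pp_166762 and Pp_72617 were 3.30, -4.81 and -4.23. With no background correction they were 0.81, -2.02 and -0.95, all short of the bounds given, and Pp_166762 no longer passed (adjusted p = 0.0570). In all, 466 of 14920 probes passed the threshold in limma, 345 higher and 121 lower in mid sporophyte, 74 of them at least 2-fold apart. With processed signals 239 passed, 143 higher and 96 lower, and with no scaling between arrays 14 passed, 6 higher and 8 lower.

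The gametophyte channels, the same tissue on the same 2 slides but from separate samples on each, differed by as much. Between them 878 probes passed the threshold, 605 higher and 273 lower on the slide of the mid arrays. Pp_222159 differed by 2.07 between the gametophyte channels on the log2 scale, Pp_94177 by 1.63 and Pp_72617 by -1.92, against 1.92, 1.63 and -1.89 in sporophyte. Pp_166762 differed by -0.22 in gametophyte, against -2.95 in sporophyte. All 466 probes moved the same way in gametophyte as in sporophyte, and 389 of them were also called there, against 16.2 for independent lists. When each sporophyte was set against the gametophyte on its own array, the ratios differed between stages for 0 probes in limma, with 613 at an unadjusted p under 0.05, and a separate-channel fit of all 12 channels also called 0, with 1035. The sporophyte count on split channels fell to 158 without early sample 2 and to 0 without any other sample. The gametophyte count fell to 58 without early sample 2, to 205 without early sample 3 or mid sample 3, and to 0 without mid sample 1 or mid sample 2.

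**Figure D3:**
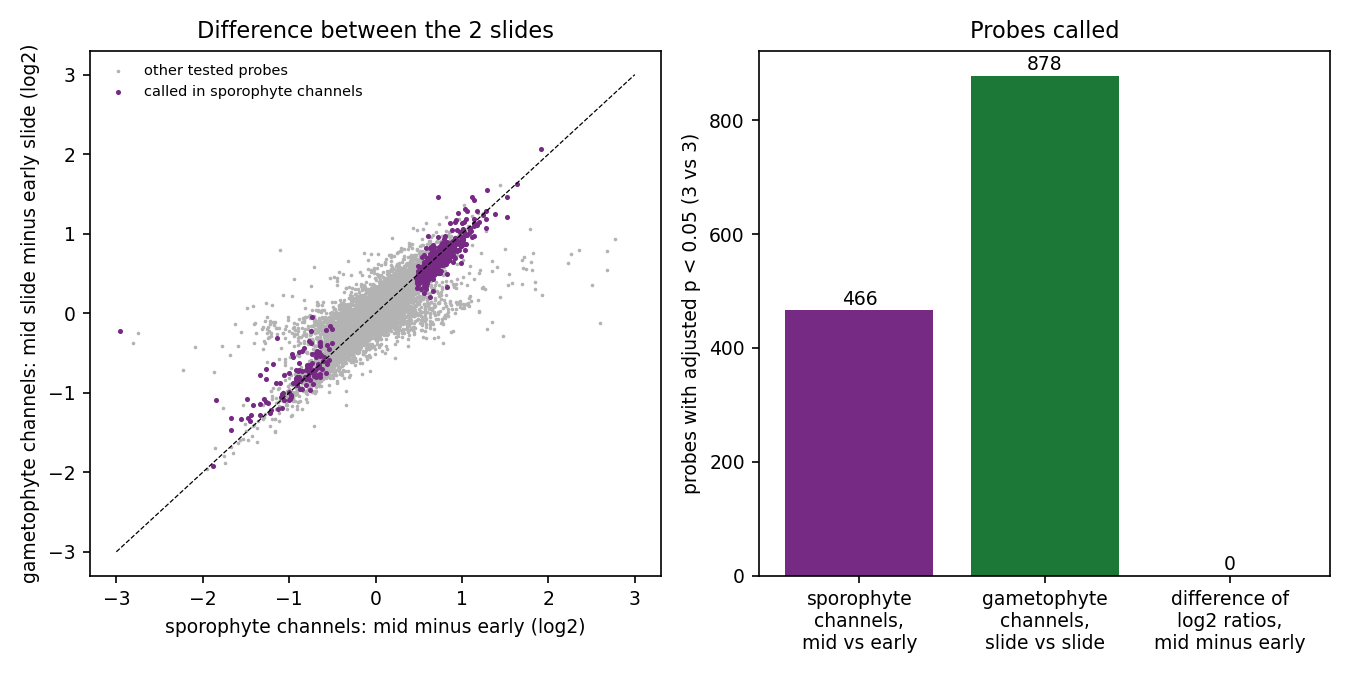
Left, the difference between mid and early arrays on the log2 scale in the sporophyte channels (horizontal axis) and the gametophyte channels (vertical axis) for 14920 probes, with the 466 called in sporophyte in purple and equality dashed. Right, the number of probes with an adjusted p under 0.05 in the sporophyte channels (466), the gametophyte channels (878) and the difference of log2 ratios (0), each 3 against 3.

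Dye orientation left a measurable trace. Of 14920 probes, 10242 passed the threshold for a dye effect, 6066 brighter in Cy5 and 4176 in Cy3, with a median absolute size of 0.19 on the log2 scale among called probes and 6 probes at 1 or more. With processed signals 6061 passed, 2847 brighter in Cy5 and 3214 in Cy3. Of all 10367 probes called between sporophyte and gametophyte, 8734 were called in the same direction with a dye term and 2 in the opposite direction. Of the 1085 probes at least 2-fold apart, 1068 were called in the same direction with a dye term. The brightest 1% of probes held 22.5% ± 1.30 of the signal in sporophyte and 19.2% ± 1.54 in gametophyte (SD, n = 6; exact two-sided p = 0.0312, adjusted p = 0.0625 over 2 measures), but in both dye-swap arrays the order turned with the dye, 18.8% against 23% and 19.5% against 24.1%.

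Probes that resemble many others were compared with the rest, a comparison chosen after the data were seen. Of the tested probes, 553 had at least 3 similar probes on the array, and their median log2 ratio exceeded that of probes without a similar probe by 0.50 ± 0.49 (SD, n = 6), with 5 of 6 pairs higher. The excess did not pass an exact two-sided sign permutation test across the pairs (p = 0.0938). The excess was 1.21, 0.03 and 0.48 in the 3 early samples and -0.12, 0.84 and 0.55 in the 3 mid samples. In the mean of both stages, 309 of these probes were called higher in sporophyte, 22 lower and 222 neither, against 5544 higher and 4823 lower among all 14920.

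**Figure D4:**
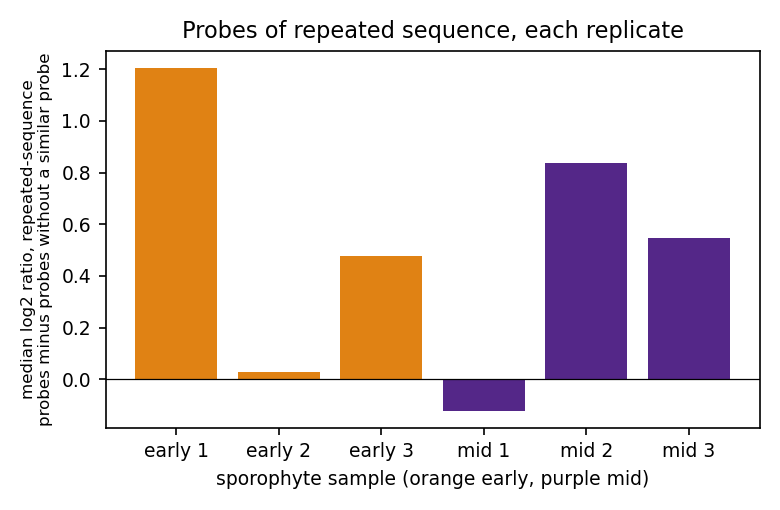
Median log2 ratio of sporophyte over gametophyte of the 553 probes with at least 3 similar probes, minus that of the 14182 probes without a similar probe (vertical axis, bars), for each sporophyte sample (horizontal axis, early in orange and mid in purple). The samples range from -0.12 to 1.21.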

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

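The tests of the slide and of the second early sample in this part were chosen after the results were seen. Across the 6 gametophyte samples, sample 1 stood apart from the rest: its mean correlation with the other gametophyte samples was 0.931, against 0.954 to 0.966, a gap of 0.673 of the whole range, past the 5% critical value of a Dixon test. It was 0.933 without probes of repeated sequence. Chance gives such a gap in about 1 in 20 groups of independent normal values, and 12 measures were examined. Mean correlations of the 6 samples share pairs with each other, so that rate may not hold for them.

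Pp_166762 differed between the stages in its ratio to gametophyte. Its log2 ratio was 2.30, 0.21 and 1.41 in the 3 early samples and -1.63, -1.14 and -1.51 in the 3 mid samples, a mid minus early difference of -2.73. The test of that difference did not pass (limma adjusted p = 0.999). On split channels its adjusted p was 0.0402. In all, 67 probes, or 0.449% of those tested, had all 3 early and all 3 mid ratios on opposite sides of 0. The difference between stages passed the test for 0 tested probes.

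The 466 probes called between mid and early sporophyte on split channels are a pattern in which slide and stage compete. The median gametophyte difference of these probes, in the direction of the sporophyte, was 0.919 of the sporophyte difference. A difference between the 2 slides would give such a share. Each slide held its own gametophyte samples, so a difference of sample batch or day between them would give it too. These cannot be told apart. A stage difference of the sporophytes as the whole cause would put the difference of ratios near the sporophyte difference of 0.73, but its median was 0.06 with an SD of 0.20 over the probes, a share of 0.0818. Single probes such as Pp_166762, which moved in sporophyte far more than in gametophyte, stay open as stage differences. The 3 against 3 samples make only 10 splits, too few for a share under 0.05: the real split gave 466 probes, 1 of 10 as large, and the highest other gave 11. For the gametophyte channels the real split gave 878 and the highest other 0.

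The second early sporophyte sample correlated in its log2 ratios at 0.946 with mid sample 1 and 0.920 with mid sample 2, at 0.787 with mid sample 3, and at 0.825 and 0.797 with early samples 1 and 3. Samples 1 and 2 of each stage had the sporophyte in Cy5 only, while sample 3 averaged both dye orientations. Shared dye bias may therefore raise the correlations among the former, which was not tested. Without probes of repeated sequence its correlation was 0.891 with early sample 1, 0.809 with early sample 3 and 0.950 with mid sample 2. On an axis from the early mean (0) to the mid mean (1) of the other samples it lay at 1.02 in the ratios, as mid-stage sporophytes in that sample could give. A swap with a mid sample would need a partner, and the lowest mid sample lay at 0.0924, but mid sample 3 also lay at 0.29, so this axis did not part the stages and neither explanation can be told apart from chance. A shift of the whole array was not decided either: the gametophyte channel of that array lay at 0.411, but that of early sample 3 lay at 0.388, and a shift common to both channels would cancel in the ratios.

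For the sporophyte in the mean of both stages against gametophyte, the 6 pairs have 32 sign splits. Only the real one, 1 of 32, gave 10367 probes, and the highest other gave 0. This is the smallest share these splits can give, so it argues against chance but does not exclude it. An offset common to the pairs, such as dye bias, could give the same share, so the splits do not test it. The early and the mid stage have 4 sign splits each, too few for a share under 0.05. The real split gave 7812 probes at the early and 8197 at the mid stage, 1 of 4 as large in either case, and the highest other gave 0.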

How the results depend on the processing

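The GC correction, the fits without probes of repeated sequence, the dye-swap pairs alone, the dye term in the difference of ratios, the dye effect without single replicates and all alternatives for the overlap of the stages were added after the data were seen. Signal over background limits these results: moss probes lay little above the negative controls, and the arrays are few. Of 104 alternative counts, 66 lay within 1.5 times the reported count. Gene lists were not run, for lack of gene descriptions, and the deposited ratios hold no split channels. The dye effect without early sample 3 or mid sample 3 was not run, since only 1 dye-swap pair would be left. The strict filter kept only probes well above background in both channels of all 8 arrays. It left out Pp_71898, Pp_72790, Pp_100530, Pp_222159, Pp_166762 and Pp_72617, so these are not counted for it. Where tested, the log2 changes of probes named against gametophyte kept their direction and stayed past the threshold. This held in all 66 alternatives at the early stage, all 66 at the mid stage and all 62 for the mean of both. Of 69 for probes named between stages, 29 stayed past it and 36 kept the direction but not the threshold, often at a like size: without single replicates Pp_94177 changed by 1.58 to 1.72, but in the difference of ratios by 0.0041. The correlation of early and mid ratios ranged from 0.880 to 0.949, and the probes called alike at both stages from 3965 to 9262. With at least 2-fold required, the counts were 1053 at the early stage, 1088 at the mid stage, 1085 for the mean of both, 74 between sporophyte stages and 87 between gametophyte slides, by construction. With no filter, more probes were tested: 17338 passed for the mean of both stages, 18464 for the dye effect and 307 between stages. The strict filter tested fewer, with 254 between stages and 402 between gametophyte slides. Counting every spot gave 888 and 1553. Processed signals gave 239 and 267, and 6061 for the dye effect. No scaling between arrays gave 14 (6 higher, 8 lower) and 69. The cause was not tested for these.

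Leaving out 1 replicate gave 4567 to 8292 probes at the early stage, 4502 to 8199 at the mid stage, 8584 to 10278 for the mean of both, 0 to 158 between stages and 0 to 760 between gametophyte slides; for the dye effect, 9730 to 9955. With 2 samples left in a stage, the spread is pooled with the other stage. Without the pairing on an array (no replicate block), 4756 probes passed at the early and 4798 at the mid stage. With the sample number as a replicate block, 0 passed between stages and 0 between gametophyte slides, with 3243 and 4005 at an unadjusted p under 0.05; deviations of same-numbered early and mid samples correlated at -0.06, 0.23 and 0.20, so the numbers do not pair them. The difference of log2 ratios, which takes the slide as a block, called 0 between stages, as did that difference with a dye term and the fit of 12 channels. In the difference of ratios the log2 change of Pp_222159 reversed to -0.15 and that of Pp_72617 to 0.035, and with a dye term to -0.15 and 0.037, as both moved alike in gametophyte.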

Other observations

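The comparison of repeated-sequence probes itself and its strand, copy and channel tests were chosen after the result was seen. Of all 28178 probes, 681 had at least 3 similar probes, and the 553 of them that were tested fell into 23 families, of which the largest held 202 tested probes. Their shift to the sporophyte appeared in both dye orientations of the swapped pairs but was larger with the sporophyte in Cy5. For early sample 3 it was 0.69 in Cy5 and 0.27 in Cy3, and for mid sample 3 it was 0.80 and 0.32. The other pairs had the sporophyte in Cy5 only, so dye bias may raise the mean over pairs. The shift was 0.64 on average with processed signals. Across the 6 pairs it did not pass the exact test (p = 0.0938). It varied within each stage, from 0.03 to 1.21 in the early samples and from -0.12 to 0.84 in the mid samples. Leaving out these probes gave 10126 called probes in the mean of both stages against 10367 with them.

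Signal level and GC content do not account for the shift: none of 10000 sets of probes matched on both reached it. Their medians lay between -0.10 and 0.05, against 0.49. The permutation p of 0.0001 is the smallest these draws can give. It takes probes as independent, though the repeated-sequence probes fell into 23 families, and it does not measure the spread across pairs. In 6 families with at least 3 tested probes of each strand, 473 probes in all, the strand with the weaker shift moved by a median of 0.689 of the stronger, which argues against transcripts from 1 strand as the cause, though in 1 family the share was 0.150. Genomic DNA in some of the sporophyte preparations, which direct labelling would also mark, could raise both strands. The shift rose with the number of similar probes (Spearman rho = 0.337 across tested probes with at least 1 similar probe, which are not independent). That range includes probes with fewer than 3 similar probes, so rho may partly restate the shift of the set compared. Whether genomic DNA is the whole cause is not decided by the channels. In the gametophyte, repeated-sequence probes lay at -0.40 against probes without a similar probe on early array 1 and at -0.21 on mid array 2. They lay at 0.15 to 0.21 on the other pairs, so their level varied in that channel too. A share of 0.41 (SE 0.12, n = 6 pairs) of the excess varied in the gametophyte channel. The gametophyte level is part of the excess, so variation in it unrelated to the sporophyte also gives a positive share. Genomic DNA in the gametophyte preparations was not tested. Genomic DNA as a part or the whole of the cause, and transcription of repeats from both strands, which was not tested, stay open.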
